A study of Mus musculus with 2 samples.

How the data were processed

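Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed by the authors for histone H3 acetylated at lysine 9 (H3K9ac), a modification found at active promoters and enhancers, in mouse hindbrain at embryonic day 14.5. Per the labels, there was a single group of 2 biological replicates. Replicate 1 was a pool of hindbrains from 24 embryos and replicate 2 a pool from 34 embryos, with males and females mixed in each. The labels give the replicates as separate biological samples, so the comparison between them covers dissection, immunoprecipitation and sequencing together.

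The deposited data used here were 4 peak lists in narrowPeak layout on the mm10 mouse assembly: a list for each replicate, a list called on the reads of both replicates together, and a list of replicated peaks. Per the file headers, the pooled list was made from the alignments of both replicates with further inputs, and the replicated list was derived from the pooled list and the lists of the replicates. The aligner, the peak caller, their versions and the rule for a replicated peak are not given in the sources used here. The authors' peak caller gave each peak a fold enrichment, which is a ratio over its control. The deposited lists also hold a −log10 p-value and a −log10 q-value for each peak, and a display score that was not used. Peak starts, ends and summit positions were taken as deposited and are printed counted from 1.

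The lowest −log10 p in the deposited lists lay between 2.00 and 2.02, so peaks had been kept down to that p-value and not by a q-value threshold. Of the deposited peaks, 13.9% in replicate 1 and 7.23% in replicate 2 had a q-value above 0.05, against 0.365% in the replicated list. The rule behind the replicated list was tested on the lists: all 34520 of its peaks were peaks of the pooled list, and 29877 (86.5%) were overlapped in both replicates by at least 50% of either peak. The other 4643 (13.5%) were not, and the criterion that admitted them is not given in the sources used here. Fold enrichments belong to the list in which they stand. They were used to rank and describe peaks within a list, and no test compared fold values between lists. The lists hold no read counts, so sequencing depth is unknown and no value has a depth-based interval.

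Peaks on chromosomes 1 to 19, X and Y were analysed. Gene positions came from GENCODE release M21 and sequence from GRCm38.p6, which is the mm10 build. Every peak end lay within the length of its chromosome. The 11 replicated peaks on unplaced and unlocalized sequences were left out of the comparisons. A promoter peak was a replicated peak overlapping the window of 1 kb either side of the annotated 5′ end of a protein-coding gene. For peak classes, the window of 1 kb around any annotated transcription start site (TSS) of any gene came first, then exon, then intron, then intergenic sequence. All peaks outside TSS windows are called distal. Where a gene's annotated 5′ end belongs to a rare upstream transcript, a peak at its usual promoter is not counted, and the alternative with any annotated TSS of the gene covers this.

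A peak counted as shared when at least 50% of its own length was overlapped by a single peak of the other list. Shares were compared with 100 random placements of the same peaks on their own chromosomes, outside assembly gaps. The smallest p these can give is 0.0099 one-sided and 0.0198 two-sided. Exact binomial (Clopper-Pearson) 95% intervals are given for shares of peaks and genes. They treat peaks or genes as independent and cover counting error only. Promoter peaks were compared with other peaks by the ratio of medians, with a bootstrap interval from 2000 draws of chromosomes.

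The 28 gene lists, with 510 entries that all matched the annotation (1 through an older symbol), were fixed before the data were examined. Promoter-peak shares were tested with a two-sided Fisher's exact test against all other protein-coding genes. Breadth was the number of bases covered by replicated peaks within 5 kb of the 5′ end. The number of distal peaks was counted within 50 kb. Both were tested two-sided against 100000 random lists of the same size, for which the smallest p is 2e-05. An exact McNemar test compared, for each list, genes with a promoter peak in a single replicate. Motif matches on either strand were counted within 250 bp of the summits of distal peaks, and in random windows outside all peaks matched on chromosome class and on GC content in steps of 2%. All families of tests had Benjamini-Hochberg adjustment, with a threshold of 0.05. Genes of a list that lie side by side can share a peak, so tests over genes treat as separate what is partly the same signal. Some genes also stand in several lists, such as Meis1, Atoh1, Ascl1, Pax6 and Pax2, so results of those lists are not independent.

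The rule for named genes was also fixed beforehand. It takes the 10 genes with the highest fold at a promoter peak, the 10 with the greatest breadth, the 10 with the most distal peaks, the 10 distal peaks with the highest fold, all Hox genes, and from each list up to 4 members with the highest fold and up to 4 without a promoter peak, in alphabetical order.

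The alternatives fixed beforehand were peaks with a −log10 q of at least 2, the upper 50% of each list by fold, other overlap rules, the list of each replicate alone, the pooled list, TSS windows of 0.5 and 2.5 kb, any TSS of a gene, random lists matched on the decile of promoter CpG content, a breadth window of 2 kb, marked genes only, distal windows of 20 and 100 kb, motif windows of 100 bp, and motif windows 3 kb away. A further alternative, replicated peaks overlapped in both replicates, was added after seeing the data.

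The computations were tested on simulated data first. With 30% and 60% of the replicate 1 peaks copied into a simulated list, the overlap recovered was 30.9% and 60.7%. In 20 simulated runs of the promoter-share test, 93.3% of the raised lists and 96.7% of the lowered lists were called. The breadth test called 90% of lists raised and 99.2% of lists lowered, and 0.82% of 244 unchanged lists. The distal-peak test called 41.7% of lists raised and 18.3% of lists lowered, so it can miss changes, lower counts above all. The planted changes were large, and each gene was drawn independently, without shared peaks or dependence on CpG content. The rates therefore do not carry over to smaller changes or to the real lists. All 5 motifs implanted in simulated windows were called. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and samtools 1.23.1 were used, with the random seed 14.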

Results

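H3K9ac was mapped in hindbrain from mouse embryos at day 14.5, the stage at which the cerebellum and the brainstem nuclei are being built from dividing progenitors and newly born neurons. The hindbrain was represented by 2 biological replicates, pools of 24 and 34 embryos. The peak list of replicate 1 held 59983 peaks and that of replicate 2 held 54881, with median widths of 338 and 380 bp. Calling on the reads of both together gave 71703 peaks. The replicated list held 34531 peaks, of which 34520 lay on chromosomes 1 to 19, X and Y, with a median width of 832 bp and a median fold enrichment of 5.20. They covered 40.7 Mb, or 1.54% of the genome outside assembly gaps. Fold enrichments given for genes are the authors' values in the replicated list unless a replicate is named.

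The first question was whether the 2 pools of embryos marked the same genes. Of 21938 protein-coding genes, 13231 had a promoter peak in both replicate lists, 309 in replicate 1 only and 353 in replicate 2 only. The 24 genes of the cerebellar granule lineage all had a promoter peak in each replicate, as did the 21 cell cycle genes and the 22 ribosomal protein genes. Genes marked in a single replicate were most numerous among microglia and macrophages (6), meninges, mural cells and mesenchyme (5) and oligodendrocyte precursors (5), and erythroid and myelinating oligodendrocyte genes had 0. Of 20 genes of meninges, mural cells and mesenchyme, 12 were marked in replicate 1 and 17 in replicate 2, and the collagen genes Col1a1 and Col3a1 and the proteoglycan gene Dcn were marked in replicate 2 only. Of 16 genes of microglia and macrophages, 6 were marked in replicate 1 and 2 in replicate 2. The complement genes C1qa and C1qb were marked in replicate 1 only and C1qc in replicate 2 only. The exact McNemar test could not decide whether lists differed between replicates: with at most 6 such genes per list, the smallest exact p possible was 0.03125, and no list could have passed after adjustment over 28 lists. For meninges, mural cells and mesenchyme all 5 genes were marked in replicate 2 only, with an exact p of 0.0625 (adjusted p = 1), the smallest that 5 genes can give.

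Over all peaks, 51.1% of the replicate 1 peaks were overlapped in replicate 2 and 51.2% of the replicate 2 peaks in replicate 1. Random placements gave means of 1.55% and 1.46% (permutation p = 0.0099 for each, the smallest that 100 placements can give, one-sided). The Jaccard index of the covered bases was 0.583. Sharing depended on peak strength. In the lowest decile of the pooled list by fold, 1.05% of peaks (95% exact interval 0.824 to 1.31%) were overlapped in both replicates, against 36.5% in the seventh decile and 95.6% (95.1 to 96.1%) in the highest. The share in the lowest decile was 4.84% when any overlap counted, and 23.1% of its peaks were overlapped in each replicate taken singly. Of the peaks in the highest decile, 97.9% lay at a TSS window.

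**Figure D1:**
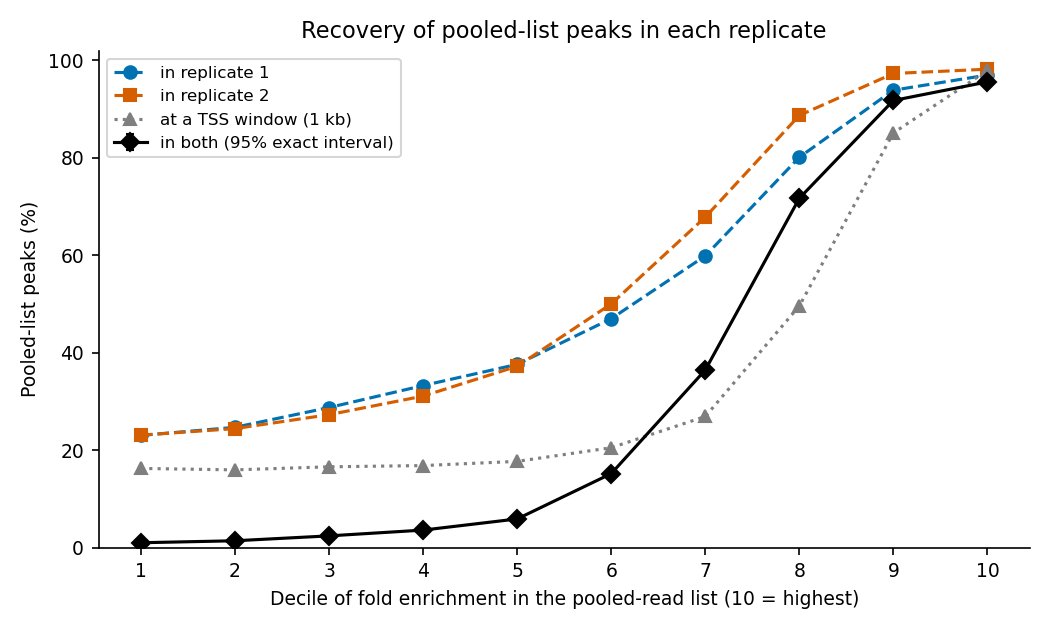
Share of pooled-list peaks (percent, vertical axis) overlapped over at least 50% of their length in replicate 1, in replicate 2 and in both, and the share at a TSS window, for each decile of fold enrichment (horizontal axis, 10 the highest); bars on the black line are exact 95% intervals and are mostly smaller than the symbols. The share in both replicates climbed from 1.05% in decile 1 to 95.6% in decile 10.

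Replicated peaks were concentrated at gene starts. TSS windows held 57.5% of them (19841 peaks), 6.05 times the mean of 9.50% for random placements, while 14.9% were intergenic against 48.4% at random. The share at TSS windows was 36.4% in the pooled list and 86.3% in the upper 50% of peaks by fold. Exons held 5.46% and introns 22.1%, against 8.17% and 33.9% at random. Each of these 4 shares lay outside the range of the 100 random placements (two-sided permutation p = 0.0198, the smallest possible). In total 13361 protein-coding genes, 60.9% (95% exact interval 60.3 to 61.6%), had a promoter peak.

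Peaks at TSS windows were also stronger and wider than the rest. Their median fold was 10.4 (interquartile range 5.22 to 16.6) against 3.56 (3.05 to 4.42), a ratio of 2.91 (bootstrap 95% interval over chromosomes 2.79 to 3.04), and 1.91 in the upper 50% of peaks by fold. Their median width was 1304 bp against 534 bp, a ratio of 2.44 (2.38 to 2.49). Both ratios were above 1 on each of the 20 chromosomes with enough peaks. Any overlap with a TSS window put a peak in that class, and a wider peak reaches a window more easily. This can add to the width ratio by construction, and how much it adds was not tested.

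Among genes ranked by promoter fold, Actb, which encodes the cytoskeletal protein beta-actin, was first with a fold of 54.9 (41.1 in replicate 1 and 52.7 in replicate 2) at chromosome 5, 142903895 to 142906766. It was followed by Srsf6, a splicing factor gene (54.4), and Kmt5b, a histone methyltransferase gene (50.1). Marcksl1 (44.9) and Marcks (43.3) encode related actin-binding substrates of protein kinase C that are abundant in developing brain. The others of the first 10 were the zinc finger gene Zfp810 (43.5), the RNA-binding protein gene Mex3b (43.0), the translation factor gene Eif4g2 (42.9), the kinase gene Map4k4 (42.9) and Bicral (42.8). All 10 had a promoter peak in both replicates. The replicates lay furthest apart at Zfp810 (27.7 and 46.5) and Map4k4 (23.2 and 41.5).

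Of the 28 gene lists, 6 had a higher share of marked promoters than other genes. All 22 pan-neuronal genes had a promoter peak (100% against 60.9% of other genes, adjusted Fisher's exact p = 9.97e-05), among them the cell adhesion gene Ncam1 (fold 35.7) and Tubb3 (31.0), the neuronal beta-tubulin. The granule lineage had 23 of 24 (adjusted exact p = 0.000575), led by Meis1 (30.6), Nhlh2 (26.1) and Zic1 (24.97), transcription factor genes of which Zic1 is needed for cerebellar growth. Neural progenitors had 21 of 22 (adjusted exact p = 0.00126), with the RNA-binding stem cell gene Msi1 at 38.1 and Id4, an inhibitor of neuronal differentiation factors, at 32.0. Hindbrain neuron regulators had 20 of 21 (adjusted exact p = 0.00126), with the nuclear receptor gene Nr2f1 at 37.0 and the Hox cofactor genes Pbx3 at 30.0 and Meis2 at 28.2. Phox2a, a regulator of noradrenergic neurons, was the member without a replicated peak at its annotated 5′ end. It had a promoter peak in replicate 1 (fold 3.80) and a replicated peak at another annotated TSS (fold 4.33). Cell cycle genes (21 of 21, adjusted exact p = 0.000157), led by the mitotic kinase gene Aurka (21.1), and ribosomal protein genes (22 of 22, adjusted exact p = 9.97e-05), led by Rpl10a (31.3), were the other lists with a higher share.

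In total 8 lists had a lower share. None of the 16 genes of Hox paralog groups 9 to 13 was marked (adjusted Fisher's exact p = 8.27e-06). Of liver genes 2 of 20 were marked (adjusted p = 4.76e-05), of gut, pancreas, kidney and lung genes 2 of 18 (9.97e-05), of germline genes 2 of 19 (5.51e-05), of muscle genes 4 of 20 (0.000783), of erythroid genes 3 of 17 (0.00126) and of microglia and macrophage genes 1 of 16 (5.51e-05), all by Fisher's exact test. The genes for albumin (Alb), alpha-fetoprotein (Afp), cardiac actin (Actc1) and the heme synthesis enzyme Alas2 had no promoter peak. Forebrain regulators, transcription factors of the anterior brain, had 8 of 23 (34.8% against 60.9%, adjusted Fisher's exact p = 0.0332). The marked ones were led by Lhx2 (fold 9.43), while Arx, Dlx1, Dlx6 and Emx2 were unmarked. The difference of forebrain regulators from other genes, -26.1 percentage points, was -22.8 with the list of replicate 2 alone and -18.3 with that of replicate 1 alone, neither past the threshold, and the call was also lost with the pooled list, a TSS window of 2.5 kb and any annotated TSS. That of microglia and macrophage genes, -54.7 points, was -24.2 and not past the threshold with the list of replicate 1 alone, and the call was also lost with the pooled list.

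The other 14 lists did not pass the test. With any annotated TSS, the Purkinje and GABAergic lineage and lysine acetylation enzymes (19 of 19 each) and Hox groups 1 to 5 (14 of 15) had a higher share, as did the Purkinje and GABAergic lineage with a TSS window of 2.5 kb. With the upper 50% of peaks by fold, monoaminergic and cholinergic neurons, endothelium, oligodendrocyte precursors and meninges, mural cells and mesenchyme had a lower share. In the replicated list their counts were 16 of 19 for the Purkinje and GABAergic lineage, 16 of 19 for lysine acetylation enzymes, 14 of 18 for late cerebellar neuron genes, 11 of 15 for Hox groups 1 to 5, and 13 of 18 for isthmus and midbrain regulators. Astrocytes had 11 of 16, oligodendrocyte precursors 7 of 11, Hox groups 6 to 8 had 5 of 8, and meninges, mural cells and mesenchyme 12 of 20. Neural crest and peripheral glia had 9 of 16, choroid plexus 9 of 17, monoaminergic and cholinergic neurons 9 of 17, endothelium 10 of 20 and myelinating oligodendrocytes 7 of 15. Within these, the acetyltransferase gene Ep300 (fold 40.5) and the deacetylase gene Hdac2 (34.8) were the strongest. The myelin gene Mbp had a fold of 19.0 at its most upstream annotated start, whereas Mag, also a myelin gene, had no promoter peak. Whether the myelin transcripts of Mbp begin at that start was not tested. The mature astrocyte genes Aqp4 and Gfap were unmarked and the glutamate transporter gene Slc1a2 had a fold of 14.6. Gabra6, a receptor subunit gene of mature granule cells, was unmarked.

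The shares followed promoter CpG content. A promoter peak was present at 0.456% of the genes in the lowest decile of the CpG observed to expected ratio and at 98.7% of those in the highest. When random lists were matched on this decile, a single list, the pan-neuronal genes, had a higher share. The other 5 higher lists were no longer past the threshold. The matched lists were themselves marked at 93.8% for hindbrain neuron regulators and 96.1% for cell cycle genes, where even a share of 100% would have given a permutation p above 0.05. For ribosomal protein genes they were marked at 89.7%, and the observed 100% gave the smallest permutation p possible there, 0.0332 (adjusted p = 0.103). They were marked at 88.6% for neural progenitors and 87.9% for the granule lineage. The calls for hindbrain neuron regulators and the granule lineage were also lost with the upper 50% of peaks by fold. With CpG matching 7 lists were lower, without microglia and erythroid genes and with isthmus and midbrain regulators added. Forebrain regulators kept their call there, at 34.8% against 88.9% for the matched lists (adjusted permutation p = 0.00028).

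**Figure D2:**
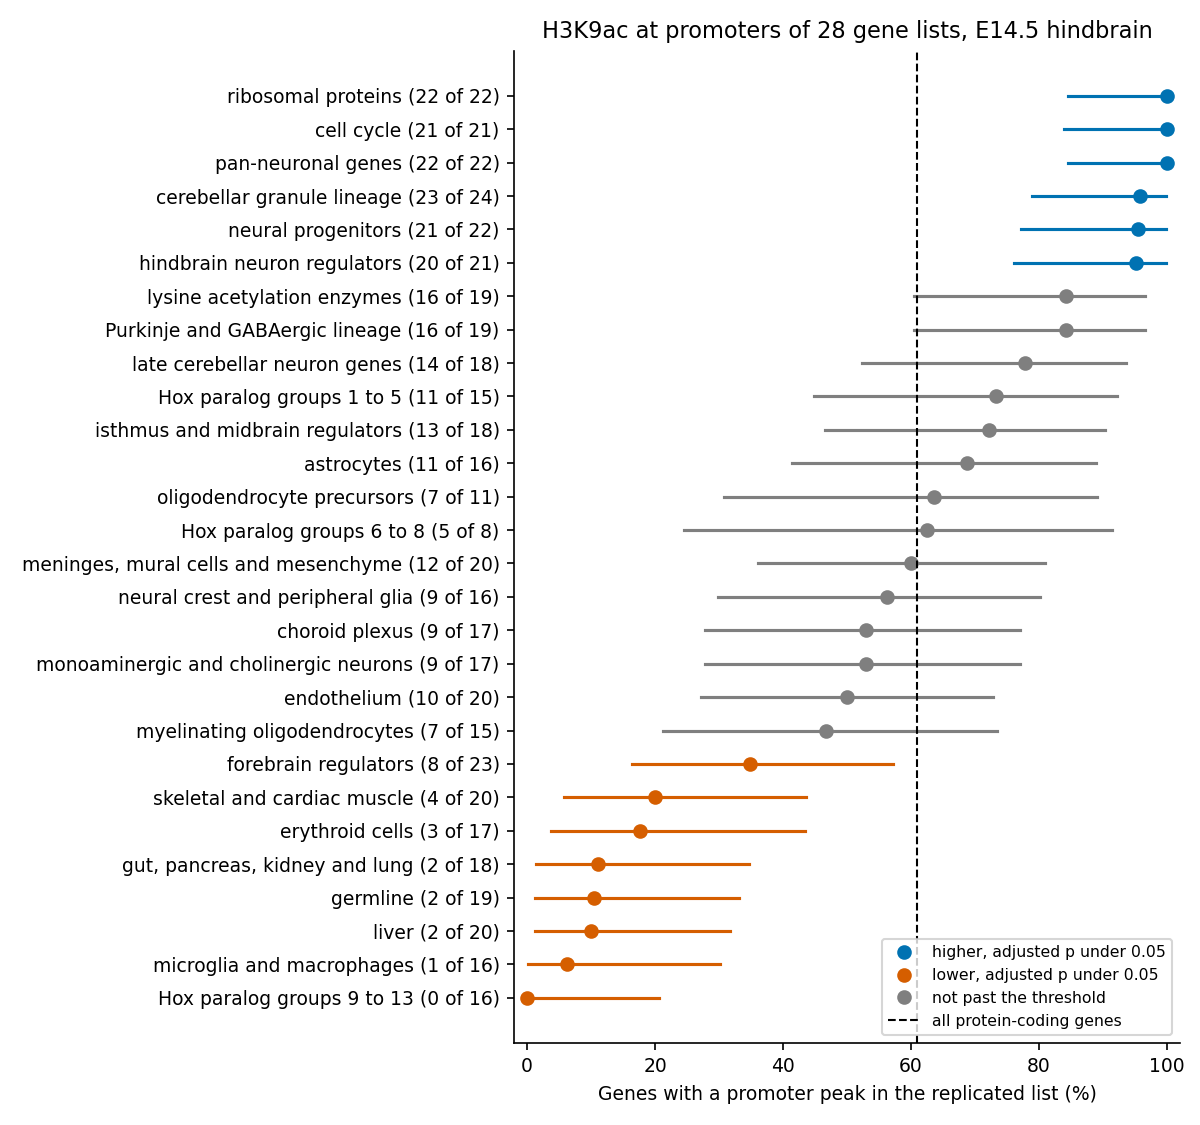
Share of genes with a promoter peak in the replicated list (percent, horizontal axis) for the 28 gene lists, with exact 95% intervals as bars, counts in brackets and the share of all protein-coding genes (60.9%) as a dashed line; blue lists were higher and orange lists lower by Fisher's exact test after adjustment. Pan-neuronal, cell cycle and ribosomal protein genes stood at 100%, and Hox groups 9 to 13 at 0%.

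The Hox genes, which give segments along the body axis their identity, were marked according to their position in the clusters. Of the 15 genes of paralog groups 1 to 5, which pattern the hindbrain, 11 had a promoter peak, against 0 of the 16 genes of groups 9 to 13, which pattern the trunk, tail and limbs (73.3% against 0%, Fisher's exact p = 1.61e-05, two-sided). Groups 6 to 8 had 5 of 8. A single peak of 54833 bp on chromosome 11, 96292628 to 96347460, contained the 5′ ends of Hoxb3, Hoxb4 and Hoxb5, reached the window of Hoxb6 and had a single fold of 23.7, and a peak of 27432 bp on chromosome 6, 52158372 to 52185803, contained that of Hoxa2 and reached the window of Hoxa1 (fold 29.5). In replicate 1, where these peaks were split, the folds were 18.6 at Hoxb3 and Hoxb4, 9.18 at Hoxb5, 3.77 at Hoxb6, 22.1 at Hoxa2 and 11.8 at Hoxa1. Hoxb2 had a fold of 27.0 and Hoxa4 one of 17.4. Further along the clusters the fold was 7.34 at Hoxa6 (3.37 in replicate 1), 6.51 at Hoxb7 and Hoxb8 (3.81 and 3.45 in replicate 1) and 3.72 at Hoxa7, and Hoxa9 and Hoxb9 had no replicated peak. In the Hoxd cluster, Hoxd1 had a fold of 4.16, and Hoxd3 and Hoxd4 shared an annotated upstream start with a fold of 4.93, against 18.6 and 12.4 when any annotated TSS was counted.

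The 4 genes of groups 1 to 5 without a promoter peak were Hoxa3, Hoxb1, Hoxc4 and Hoxc5. When any annotated TSS of a gene was counted, Hoxa3 (fold 29.5), Hoxc4 (13.03) and Hoxc5 (12.2) were marked, so that 14 of 15 were marked and Hoxb1 was the exception. Neighbouring Hox genes share peaks, so the exact test overstates the number of independent genes. In replicate 2 alone, Hoxb9 had a promoter peak with a fold of 3.21.

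**Figure D3:**
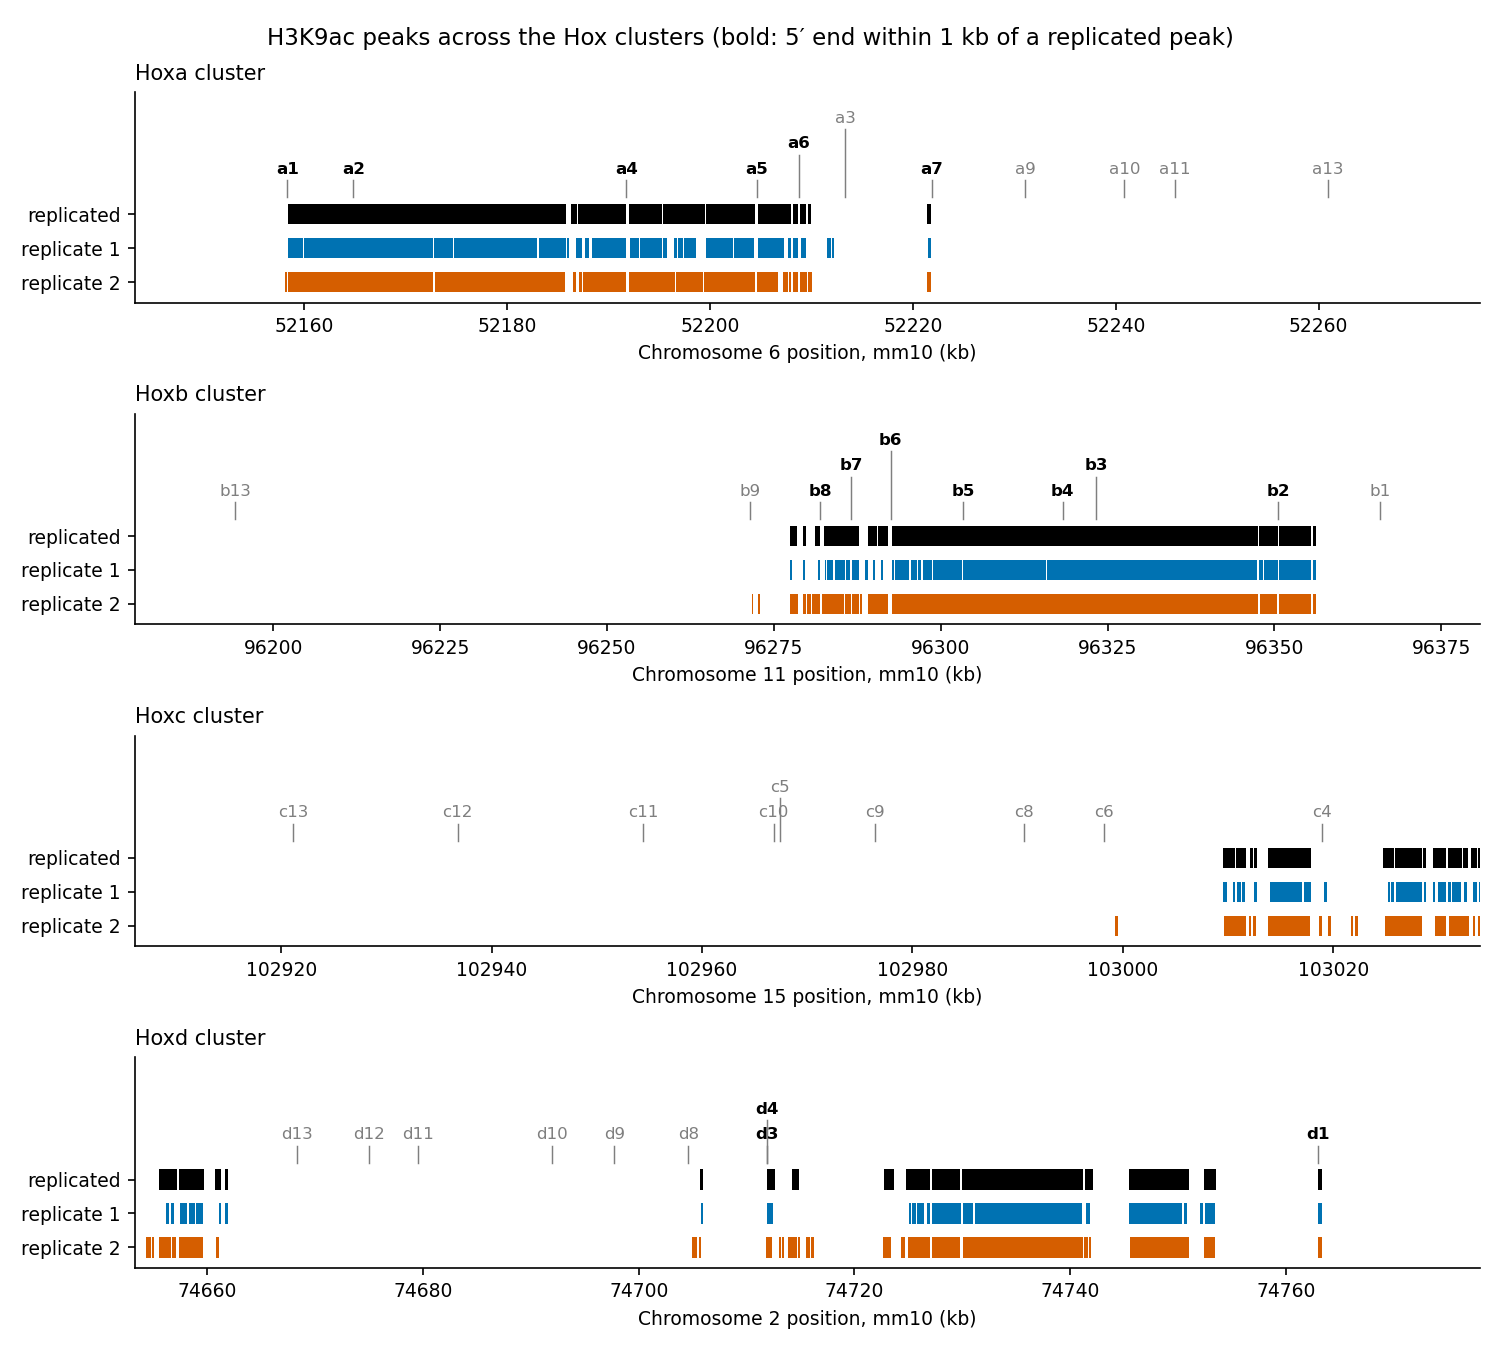
Peaks of the replicated list (black), replicate 1 (blue) and replicate 2 (orange) across the Hoxa, Hoxb, Hoxc and Hoxd clusters, drawn to scale from 15 kb before the first to 15 kb after the last 5′ end (horizontal axis, mm10 position in kb); vertical ticks mark annotated 5′ ends, in bold where a replicated peak lay within 1 kb. Replicated peaks lay across the Hoxa1 to Hoxa6 and Hoxb2 to Hoxb8 parts, and none of the genes of groups 9 to 13 had a replicated peak at its 5′ end.

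Breadth, the number of bases covered within 5 kb of the 5′ end, was greatest for regulators of the hindbrain. Hindbrain neuron regulators had a mean of 5619 bp (SD 3063 over 21 genes) and Hox groups 1 to 5 one of 5462 bp (SD 4381 over 15 genes), against 1484 bp for random lists (adjusted permutation p = 5.6e-05 for each, from the smallest p possible). Neural progenitors (4641 bp), the granule lineage (4448 bp), the Purkinje and GABAergic lineage (4388 bp), pan-neuronal genes (4335 bp) and ribosomal protein genes (3079 bp) reached the same p. Hox groups 6 to 8 (3557 bp, adjusted permutation p = 0.0021) and isthmus and midbrain regulators (2650 bp, adjusted p = 0.00593) completed the 9 broader lists. The calls for both of these were lost with the upper 50% of peaks by fold and with a window of 2 kb, and that for isthmus and midbrain regulators also with CpG matching. The window of 10000 bp was fully covered at 9 genes: Hoxa2, its neighbour 5730596B20Rik, Hoxb3, Hoxb4, Hoxb5, Meis2, Ebf3, a regulator of hindbrain and cerebellar neurons, Lhx1, a regulator of Purkinje cells, and Slc32a1, the transporter gene that loads GABA and glycine into synaptic vesicles. Tnrc18 followed with 9927 bp.

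A further 9 lists were narrower than random lists. All of them but the endothelial genes also had a lower promoter share. A gene without a promoter peak has no covered bases within 1 kb of its 5′ end, so these results partly repeat the earlier ones. Hox groups 9 to 13 had 0 bp. Germline (67.9 bp), microglia (144.5 bp), erythroid (210.1 bp), gut, pancreas, kidney and lung (229.9 bp), forebrain (392 bp), liver (399 bp) and muscle genes (478 bp) had adjusted permutation p between 5.6e-05 and 0.00153. Endothelial genes had 768 bp (adjusted permutation p = 0.0349), with the receptor gene Kdr at 1509 bp and Emcn at 0 bp. The endothelial difference from random lists, -717 bp, was -534 bp and not past the threshold with the list of replicate 2 alone, and was also not past it with the pooled list. The calls for microglia, erythroid and liver genes were lost with CpG matching, and that for muscle genes with random lists drawn from marked genes only. Among marked genes, forebrain (8 genes), erythroid (3) and endothelial genes (10) kept the call. The erythroid value rests on 3 genes, the fewest for which a value was computed. The other narrower lists (Hox groups 9 to 13, germline, microglia, liver, and gut, pancreas, kidney and lung) had too few marked genes for a value.

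**Figure D4:**
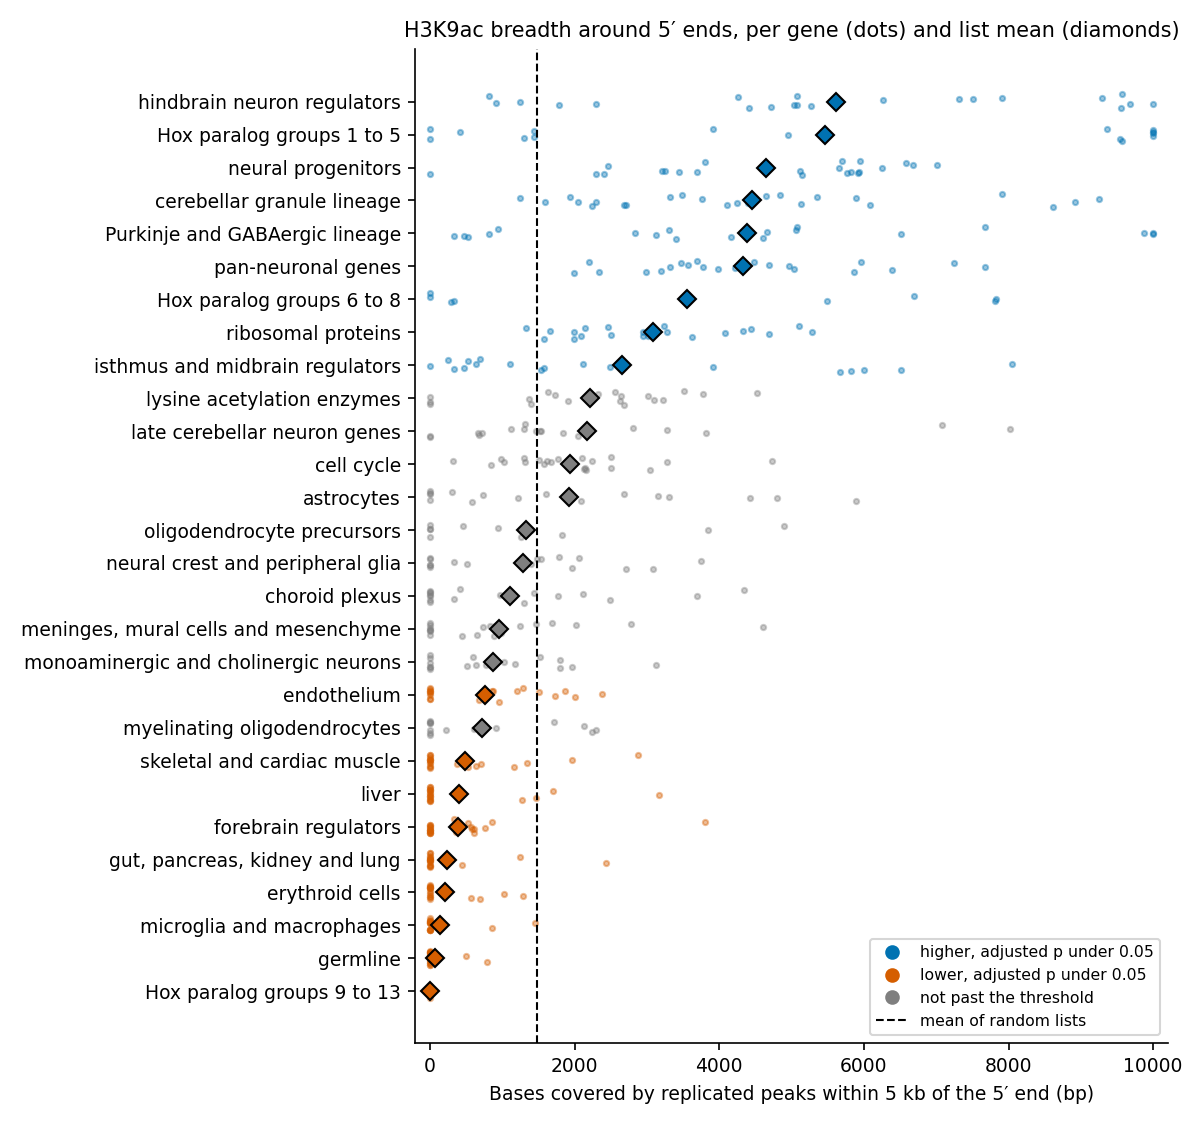
Bases covered by replicated peaks within 5 kb of the 5′ end (bp, horizontal axis) for each gene (dots, jittered vertically) of the 28 lists, with list means as diamonds and the mean of random lists as a dashed line; blue lists were broader and orange lists narrower by the permutation test after adjustment. Hindbrain neuron regulators had the highest mean, 5619 bp, and Hox groups 9 to 13 lay at 0 bp.

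Distal peaks, which include candidate enhancers, were counted within 50 kb of each 5′ end. In total 8 lists had more than random lists, whose means lay between 0.935 and 0.941 per gene, and 0 lists had fewer. The test had little power for lower counts. Hindbrain neuron regulators had 4.05 (SD 3.12), the granule lineage 3.54 (SD 3.04), isthmus and midbrain regulators 3.50 (SD 3.71) and neural progenitors 3.14 (SD 2.53), with an adjusted permutation p of 0.00014 each. Hox groups 6 to 8 had 4.38 (adjusted permutation p = 0.00084), the Purkinje and GABAergic lineage 2.89 (0.00084), Hox groups 1 to 5 had 2.87 (0.00344) and Hox groups 9 to 13 had 2.31 (0.027). Neighbouring Hox genes share windows, so the same distal peaks were counted for several genes. Hoxc6 and Hoxc8 had 10 each and Hoxc4 had 13. The random lists were drawn without regard to position, so the Hox p-values overstate the number of independent genes. Runs of neighbouring genes were tested for groups 9 to 13 only. Among list members, Nr2f1, Meis2 and Pbx3 had 8 each, and Pax2, which marks the isthmus and GABAergic interneurons, had 14. Pax2 stands in both the isthmus and midbrain list and the Purkinje and GABAergic list, so its peaks raised both means. The call for Hox groups 9 to 13 was lost in 5 of 8 alternatives, the list of replicate 1 alone among them (difference from random lists 1.87, against 1.37 in the replicated list). Those for Hox groups 1 to 5 and 6 to 8 were lost with the pooled list, with the upper 50% of peaks by fold and with random lists drawn from marked genes only, and that for groups 6 to 8 also with a window of 20 kb. Those for isthmus and midbrain regulators and for the Purkinje and GABAergic lineage were lost with the upper 50% of peaks by fold only.

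Over all genes, Bcl11b, a transcription factor gene of neurons and T cells, and Flrt1, an adhesion receptor gene, had the most distal peaks, 16 each. Ahdc1, the Polycomb gene Cbx4, the cold-inducible RNA-binding protein gene Cirbp, Pipox and Racgap1 had 15, and 1600002K03Rik, the ion channel gene Asic1 and Cxxc5 had 14. Flrt1 itself had no promoter peak in the replicated list, and Pipox had a fold of 3.08. Cirbp and 1600002K03Rik are close together on chromosome 10 and share most of their windows, as do Racgap1 and Asic1 on chromosome 15. The strongest distal peak, with a fold of 26.7, was intergenic on chromosome 1, 86487671 to 86489085, 38.3 kb from the 5′ end of Ptma. Others of the first 10 lay 83.3 kb from Arhgap32 (fold 26.3), 73.1 kb from Spag6 (26.1), 5.46 kb from Zfp869 (25.8), 59.1 kb from Ppara (25.8), 51.5 kb from Prdm2 (24.8), 2.87 kb from Mos (24.3), 33.1 kb from Pum2 (23.8), 85.1 kb from Zfp947 (23.3) and 34.5 kb from Acot11 (23.3). The peak near Ppara lay in an intron and was 12423 bp wide. All 10 overlapped a peak in each replicate.

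Motif content set distal peaks apart from other sequence of the same GC content. Of 14679 distal peaks, 13607 had a complete window with a GC-matched counterpart and were used. The ratios describe those peaks and not the ones left out. The matched windows were not matched on CpG content or on repeats, and the effect of either on the ratios was not tested. In these windows, 13 of 25 motifs were more frequent than in matched windows and 2 were less frequent. The core site of the insulator protein CTCF was found in 2.20% of peak windows against 0.382% (ratio 5.75, adjusted Fisher's exact p = 4.47e-43). The RFX X-box GTTGCCATGG followed with a ratio of 3.13 (adjusted Fisher's exact p = 1.18e-10), then NRF1 with 2.80, the GC box of SP and KLF factors with 1.91, MEF2 with 1.90 and the CREB site with 1.77. The homeodomain site TAATTA was in 13.1% of windows against 7.83% (ratio 1.68, adjusted Fisher's exact p = 4.69e-46), the POU octamer had a ratio of 1.67, ACAAAGG of SOX and TCF factors 1.59, FOX 1.33 and the E-box CAGCTG 1.31. SOX ACAATGG and MEIS reached 1.12 each (adjusted Fisher's exact p = 0.0151 and 0.0265). The proneural E-box CAGATG did not pass the test (37.2% against 36.7%, adjusted Fisher's exact p = 0.49), nor did sites of PBX-HOX (ratio 0.990), GATA (1.00), TEAD (0.969) and SMAD (0.969). Sites of AP-1 (ratio 0.847) and NF-Y (0.824) were less frequent. With the upper 50% of peaks by fold the calls for AP-1, NF-Y, NRF1, RFX, CAGCTG, FOX and MEIS were lost. With windows of 100 bp those for RFX, MEIS and AP-1 were lost, and with windows 3 kb away those for NF-Y, SOX ACAATGG and MEIS. With the list of replicate 1 alone the ratios of CREB sites (1.24) and AP-1 (0.948) were not past the threshold, and that of SOX ACAATGG was past it with neither replicate's list (1.02 and 0.993). The CAGATG ratio was past it with each replicate's list, at 1.03. It was also past it, above 1, with the pooled list, with windows of 100 bp and with windows 3 kb away. With the upper 50% of peaks by fold it was past the threshold in the other direction, at 0.799. That of TEAD was past it with each replicate's list, at a ratio below 1.

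The position of the match relative to the summit differed between motifs. This profile was computed after the motif shares were seen and was not tested. CTCF sites within 50 bp of the summit were 0.222 times as frequent as in matched windows (2 matches against 9), and from 200 to 250 bp they were 14.8 times as frequent (118 against 8). RFX sites went from 1.43 to 5.29 over the same bins. The E-box CAGCTG went the other way, from 1.54 within 50 bp to 1.11 at 200 to 250 bp. With windows of 100 bp around the summit, CTCF sites were less frequent than in matched windows, at a ratio of 0.281, past the threshold in that direction. Those matched windows were drawn anew. In the profile, the bin from 50 to 100 bp held 10 CTCF matches against 9, so the size of that ratio is not given by the profile. In the same windows the ratios of NRF1 (0.40) and CREB sites (0.889) also lay below 1. Against windows 3 kb away, which were not matched on GC content, those of TAATTA (0.988) and FOX (0.987) did.

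**Figure D5:**
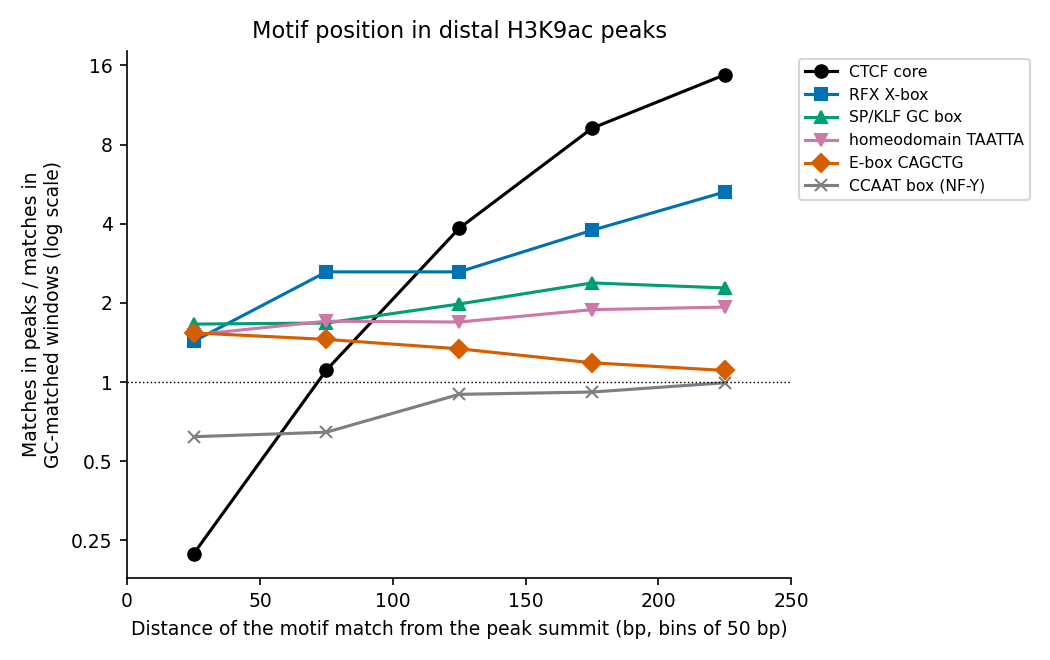
Number of motif matches in 13607 distal peak windows divided by the number in matched windows (vertical axis, log scale) against the distance of the match from the summit in bins of 50 bp (horizontal axis), for 6 motifs; single counts are small for CTCF and RFX. The CTCF ratio went from 0.222 at the summit to 14.8 at 200 to 250 bp, and the CAGCTG ratio from 1.54 to 1.11.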

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

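Outside the chromosomes used in the comparisons, the replicated list held 11 peaks on unplaced and unlocalized sequences, a signal in data that no comparison used. Their number is above the limit of 3 that a count of 0 allows, which shows only that peaks were present, since no expected number was available. The list of replicate 1 had 12 peaks there and that of replicate 2 had 11. The strongest, with a fold of 12.5, lay on an unlocalized sequence of chromosome 4, and 4 lay on an unlocalized sequence of the X chromosome with folds of 6.33 to 10.8.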

How the results depend on the processing

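Leaving out peaks without an overlap in both replicates was chosen after seeing the data. Of 131 values that answer a comparison, 122 kept their direction and call or, without a test, stayed within 1.5 times for counts and within the exact 95% interval for decile recovery, and 9 did not. Recovery in the lowest decile was 4.84% with any overlap, and in the highest decile 100% with any overlap and 94.9% with reciprocal overlap. Lists with a higher promoter share numbered 1 with random lists matched on CpG content. Lists with lower breadth numbered 5 among marked genes, where 5 lists had too few genes for a value. The lower ones included monoaminergic neurons and meninges, which had no call in the replicated list. Lists with more distal peaks numbered 3 with the upper 50% by fold and 5 among marked genes. Motifs numbered 8 higher and 1 lower (CAGATG) with the upper 50% by fold, where 1656 distal windows were left after the fold limit and the GC matching together. Any overlap is a looser rule by construction, the upper 50% and the marked genes are smaller sets, and for the CpG matching the cause was not tested. Across single lists, 233 of 280 promoter shares, 146 of 157 breadths and 57 of 71 distal counts kept direction and call. Breadth, distal-peak and motif results without a call in the replicated list are left out of these numbers, a choice made after seeing them. The motif CAGATG, also without a call, was treated apart and is not among the 62 motif ratios counted next. Direction changed in 5 of 90 such breadths, 20 of 176 distal counts and 22 of 62 motif ratios. Of these values 12, 7 and 5, in that order, were past the threshold, among them lower breadth of monoaminergic neurons in 5 alternatives and of meninges in 4, and more distal peaks at pan-neuronal genes in 3. A promoter peak at a named gene was present or absent alike in 1912 of 2043 values and changed in 131. No paired analysis was possible because there was a single group.

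Differences in promoter share from other genes that turned were, in percentage points, as follows. With CpG matching they were -4.01 for Hox groups 1 to 5, -26.5 for Hox groups 6 to 8, -8.81 for the Purkinje lineage, -4.33 for oligodendrocyte precursors, 0.644 for myelinating oligodendrocytes, -17.6 for isthmus regulators, past the threshold, and 2.85 for erythroid genes. With the upper 50% by fold they were -2.17 for Hox groups 1 to 5, -5.50 for Hox groups 6 to 8, -46.4 for oligodendrocyte precursors, past the threshold, -18.0 for astrocytes and -11.1 for isthmus regulators. Oligodendrocyte precursors also gave -6.32 with the q-value minimum, -14.8 with peaks overlapped in both replicates and -14.4 with windows of 0.5 kb. Leaving out a replicate gave -1.72 to 23.1 for meninges and -11.9 to 0.781 for neural crest; the cause was not tested. Meninges also gave 11.6 with the pooled list, and 0.141, 2.30 and 10.4 with windows of 0.5 kb, 2.5 kb and any TSS. Monoaminergic neurons gave 2.00 with 2.5 kb and 5.95 with any TSS, neural crest 4.11 with any TSS, and choroid plexus 1.31 with the pooled list. Apart from the erythroid value, none of these lists had a call at the settings of the report.

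Motif ratios that turned were 0.281 for CTCF, 0.40 for NRF1 and 0.889 for CREB sites with windows of 100 bp, and 0.988 for TAATTA and 0.987 for FOX with windows 3 kb away, whose GC content was 45.7% against 50.8%. CAGATG gave 0.799 with the upper 50% by fold, past the threshold, and 0.996 with peaks overlapped in both replicates. SOX ACAATGG gave 0.993 to 1.02 on leaving out a replicate and 0.985 with the pooled list. The cause was not tested, except that CTCF, NRF1 and CREB matches near summits were few compared with those further out.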

Other observations

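The replicated peaks were ranked by width after their values were seen. After the peaks in the Hoxb and Hoxa clusters came a peak of 20064 bp nearest to Mef2c, a regulator of neuronal differentiation, with a fold of 45.4, and peaks at Meis2 (19514 bp), near the glial and granule cell regulator Nfib (18879 bp), near Zfhx3 (16863 bp), at Mn1 (16387 bp), Lhx1 (16081 bp), Bcl11a (16036 bp) and Meis1 (15082 bp). The peaks near Mef2c, Nfib and Zfhx3 held no outermost annotated 5′ end of a protein-coding gene. The folds of the peaks near Mef2c (45.4) and Zfhx3 (29.6) were above that of the strongest distal peak (26.7), so both overlapped a TSS window. The peak near Nfib (fold 25.1) was not among the 10 strongest distal peaks, whose folds reached down to 23.3. It therefore overlapped a TSS window too. Which genes those TSSs belong to was not examined. The peak near Mef2c was a single peak in each replicate, of 20095 and 19901 bp, whereas the Hoxb peak was split into 8 peaks in replicate 1, the widest of 31502 bp.

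Coverage around the 5′ ends of marked genes was lopsided. The first 1 kb downstream was covered over 86.7% on average and the first 1 kb upstream over 55.9%, and from 1 to 5 kb the values were 17.4% downstream and 5.90% upstream. The 5′ end used was the outermost annotated start of each gene. A promoter in use at another start of the gene therefore lies downstream, which can add to this difference by construction. How much it adds was not tested. The X chromosome had 5.10 replicated peaks per Mb and a promoter peak at 45.4% of its genes, the lowest values apart from the Y chromosome, and chromosome 11 had 24.4 peaks per Mb, the highest.

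The tests on abundant tissue genes, on other annotated TSSs and on compact runs of genes were chosen after the results they measure were seen; the other tests below were set before. The samples formed a single group, so no biological explanation was tested.

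Promoter peaks were found at 14 of 110 genes from the lists of microglia, erythroid cells, muscle, liver, gut and germline, among them Mylpf of muscle (fold 21.3), Foxa3 of liver (18.1), Hexb of microglia (10.8) and Dazl of the germline (7.91). Cells of those tissues in the dissected samples would bring marks at their most active genes. Of 12 abundant genes 0 carried a promoter peak, but these had been picked from 4 of the 6 lists and without the 10 marked members of those 4, so the count decides nothing and that source stayed open. Another protein-coding gene's TSS lay at the peak for 35.7% of the 14, against 20.6% of other marked genes (Fisher's exact p = 0.183), too few genes to decide; these 5, such as Mylpf beside Tbc1d10b and Foxa3 beside Sympk, had a median fold of 15.7. For the other 9, with a median fold of 4.23, a peak of any other annotated TSS is excluded, since 9 of 9 had no annotated TSS of another gene within 1 kb of the peak. What marks those 9, including Klf1, Myod1 and Dazl, stayed open.

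Distal peaks around Hox genes of groups 9 to 13 were more frequent than around random lists, although none of the genes was marked. Their 37 gene and peak pairs came from 15 distinct peaks with a median fold of 3.56. Random runs of neighbouring genes reached the observed mean of 2.31 with a one-sided permutation p of 0.0463, which by itself argues against shared peaks as the whole cause, but such runs span more sequence than a Hox cluster. Runs spanning at most 2 times the Hox run had a mean of 1.25 and reached it with a one-sided permutation p of 0.115. The excess may therefore come from the compact layout of the clusters in peak-rich sequence, and the part due to shared peaks cannot be told apart from it, since the 2 kinds of run differ in span.

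Replicated-list peaks without an overlapping peak in both replicates numbered 4434, or 12.8% of the list, 178 of them without an overlap in either. By fold they were weak: 99.6% lay in the lower 50% of the list by fold, with a median of 3.15 against 6.33 for the rest, and 22.1% lay at a TSS window against 62.7%. A lower yield of a single replicate stayed open. Among peaks overlapped in exactly 1 replicate, 2421 lacked replicate 1 and 1835 lacked replicate 2, so replicate 1 was lacking in 56.9%. This share lay below the limit set beforehand for arguing against that explanation, but the split was uneven, so the test does not decide. In the list of replicate 1, 72.7% of peaks had a −log10 q of at least 2, against 79.2% for replicate 2. The list of replicate 1 held more peaks, however. Weak peaks near the calling threshold stayed open as an explanation, since 95.1% of them had a −log10 q of at least 2, past the lowest p-value kept in the list, and their strength in the replicates was not tested. The share of genes with a promoter peak depended little on them, with 13209 genes when only peaks overlapped in both replicates were kept, against 13361.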
